A study of Sinapis alba with 12 samples.

How the data were processed

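Root transcriptomes of white mustard (Sinapis alba), an oilseed and condiment crop of the cabbage family, were measured by RNA sequencing in 12 libraries. Per the labels, 17 seeds were germinated per dish in darkness for 3 days on filter paper wetted with 5 mL of medium at pH 6.1 to 6.3, and total RNA was taken from the roots. The media were water, water with silver nanoparticles (Ag NPs) at 1000 mg/L, calcium nitrate given as its tetrahydrate at 2.35 g/L, and calcium nitrate with Ag NPs. Each library was assigned to a group from its treatment label, which gave 4 groups of 3 libraries. The labels do not say whether the libraries of a group came from separate dishes, so p-values measure only the spread between these libraries, which may be technical.

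Reads were trimmed with Trimmomatic and quantified with Salmon 1.3.0, per the submitters' processing notes. The Trimmomatic version, the transcript set, the genome build, the strand setting and the Salmon options are not given in the sources used here. RNA was extracted with a column kit and libraries were made with a KAPA kit, per the labels' protocols. Salmon splits reads that match several transcript models among them, so the estimated counts the authors deposited need not be whole numbers. TPM values, which the authors deposited beside the counts, were used to find the most abundant gene described in the closing section. They also weighted effective lengths over the models of a gene where effective lengths served as an offset. The coding length and the effective length of each model are given per the file headers. All 51227 model lengths are multiples of 3, so the models hold coding sequence without untranslated regions, and lengths are called coding lengths.

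Estimated counts were summed over the models of a gene, recognised by the number after the last point of the identifier, which turned 51227 models into 49513 genes. The sums were rounded to whole numbers. A sum more than 0.01 away from a whole number in any library was taken as a sign of reads shared with another model, and 61% of the tested genes had such a sum in at least 1 library. A whole sum does not exclude sharing. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few reads were removed by filterByExpr, which left 31675 genes, libraries were scaled by TMM, and 1 quasi-likelihood model with a coefficient per group was fitted to all 12 libraries. The comparisons were Ag NPs against none in water, Ag NPs against none in calcium nitrate, calcium nitrate against water, both treatments against water, and the interaction, which is the Ag NP effect in calcium nitrate minus that in water. Calcium nitrate was also compared with water among the libraries with Ag NPs, which was not planned and was not repeated under the other settings. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Log2 fold changes are edgeR's fitted values. The test gives no standard error. Their values marked SE are approximate, derived as the absolute log2 fold change over the square root of the test's F statistic. CPM means counts per M reads after TMM scaling. Principal components were computed from log2 CPM with a prior count of 2.

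Depth ran from 15.2 M to 29.3 M estimated reads per library. A count of 3 reads, the upper limit that a count of 0 allows, corresponded to 0.103 to 0.189 CPM in a single library. Where all 3 libraries of a group were at 0, the fold is given as a lower bound against 3 reads over the whole group. Such bounds cover counting error only, and after the data were seen they were also computed with each library of the group with reads left out. On counts simulated from the real means, depths and spread, edgeR recovered 23% of 100 genes changed 2-fold and 63% of 100 changed 4-fold for Ag NPs in water, 29% and 66% for Ag NPs in calcium nitrate, 33% and 72% for calcium nitrate, 34% and 65% for both treatments, and 3% and 41% for the interaction. Fewer genes were changed in each simulation than were called in any comparison except the interaction, and recovery with more changed genes was not simulated. The 12 pairs of libraries within groups differed by more than sampling noise, with chi-square values per degree of freedom between 15.9 and 41, so no library was counted as a duplicate.

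The identifiers come without gene names in the files, and no name table was used here. The 26 gene lists fixed before the data were examined, 486 genes among them for ethylene, nitrate, metals, oxidative stress and markers of shoot and seed tissue, are defined by Arabidopsis loci and symbols. They matched no identifier, so these lists are not analysed here. The rule for named genes, fixed at the same time, allowed at most 2 identifiers that rose and 2 that fell per comparison where no names are given. It took the largest log2 fold changes among called genes with a mean of at least 1 CPM over the 6 libraries compared and no overlap between the groups' libraries. Sialb.0866s0017 and 7 short genes in the closing section were chosen after their values were seen.

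The other settings chosen before the data were examined were DESeq2 1.42.0, limma-voom with limma 3.58.1, DESeq2's size factors inside edgeR, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a fit of only the 2 groups compared, models left unsummed, a limit of 1 on the absolute log2 fold change, an adjusted p under 0.01, and leaving out each library in turn. DESeq2 was run without filterByExpr and applied its own filter, so its gene set differed from that of edgeR. Effective lengths as an offset, libraries thinned to 15.2 M reads, and a fit of only the genes with whole sums were added after the data were seen. For comparisons that share libraries, the correlation and covariance of fold changes with no effect at all were taken from 20 simulated sets. After the data were seen, both were also computed from mean log2 CPM with the shared libraries divided between the comparisons. The comparison of the nitrate effect with and without Ag NPs in held-out libraries was also devised after the data were seen. It chose 500 genes in each direction from 2 libraries per group and measured them in the remaining library of each group, over all 81 combinations. It was repeated with each library left out of both steps, in 54 combinations per library. On simulated data with a true ratio of 1 it returned a median of 0.988, and with a true ratio of 0.5 a median of 0.509.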

Results

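The data are transcript abundances in roots of white mustard seedlings germinated for 3 days in water or in a calcium nitrate solution, each with or without silver nanoparticles (Ag NPs). Each of the 4 groups had 3 libraries. The series' title names ethylene signalling and root elongation as its subject. The mean depth was 27.3 ± 1.88 M estimated reads in water, 19.6 ± 1.95 M in water with Ag NPs, 16.9 ± 1.65 M in calcium nitrate and 19.2 ± 4.46 M in calcium nitrate with Ag NPs (SD, n = 3 each). Between 35667 and 36681 genes had reads in a library.

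The libraries grouped by treatment. Spearman correlations of log2 CPM were 0.962 to 0.973 for the 12 pairs within groups and 0.922 to 0.961 for the 54 pairs between groups. The first principal component held 23.3% of the variance and the second 18.3%. On the first component calcium nitrate libraries had the highest scores, with a mean of 79.3 ± 14.7 (SD, n = 3) against -23.8 ± 7.59 in water. Calcium nitrate libraries with Ag NPs had a mean of 4.27 ± 10.3 and water libraries with Ag NPs one of -59.7 ± 9.33. On the second component the Ag NP libraries scored below their media without Ag NPs, at -25.2 ± 17 against 68.3 ± 18.3 in water and at -50.8 ± 12.3 against 7.73 ± 3.72 in calcium nitrate. Of 10 differences between groups on these components, 9 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow, and a Benjamini-Hochberg adjusted p of 0.111.

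**Figure D1:**
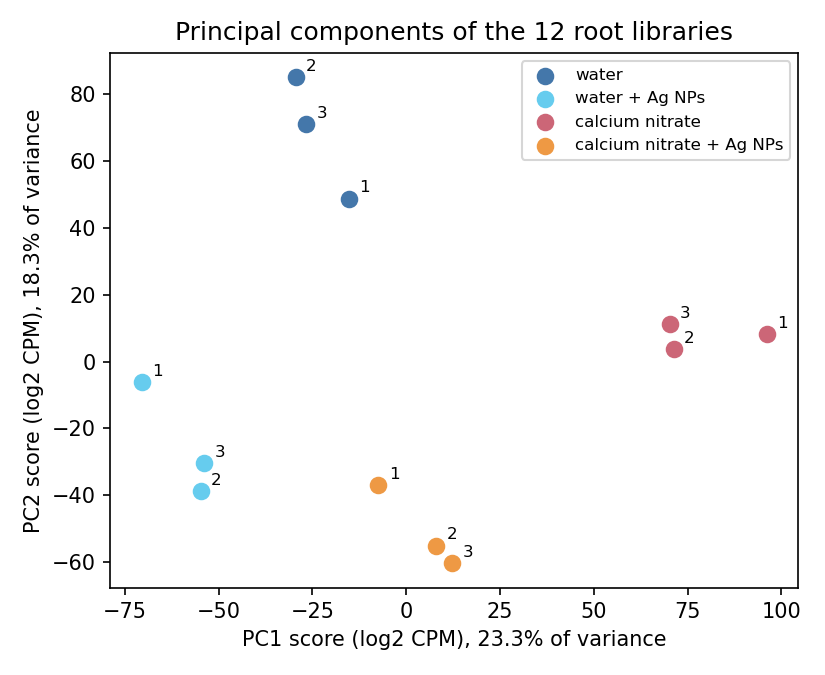
Scores of the 12 libraries on the first and second principal component of log2 CPM, coloured by group, with replicate numbers that only name the libraries. Calcium nitrate libraries lie between 70.2 and 96.2 on the first component, and calcium nitrate libraries with Ag NPs between -7.39 and 12.2.

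Ag NPs in water changed 813 genes, of which 358 rose and 455 fell. The genes that rose did so by a larger margin, with a median log2 fold change of 2.19 against -1.19 for those that fell. Sialb.0188s0410 had no reads in the 3 water libraries and a mean of 4.13 ± 2.83 CPM (SD, n = 3) with Ag NPs, at least 111-fold higher. Sialb.0611s0003 rose from 0.052 ± 0.0599 to 7.69 ± 7.17 CPM. In the other direction, Sialb.0002s0228 fell from 4.19 ± 0.571 CPM to no reads in any of the 3 Ag NP libraries, at least 79.6-fold lower, and Sialb.0062s0109 fell from 3.37 ± 3.39 CPM to no reads, at least 64-fold lower.

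The calls come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 31675 genes. Adjusted p values by this test were 0.00885, 0.0131, 0.00429 and 0.0152 for the 4 genes in the order named. Each was separated in 3 against 3 libraries, which the rule for named genes required, so separation adds no support. At least 2-fold changes were found for 291 genes that rose and 286 that fell. The call of Sialb.0611s0003 was lost without water replicate 2 or 3, with adjusted p values of 0.0559 and 0.0649 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while its log2 fold change was 6.52 and 6.97 there against 7.11 with all libraries. That of Sialb.0062s0109 was lost without Ag NP replicate 2, with an adjusted p of 0.0502 by the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment and a fitted log2 fold change of -9.12 with and without it. The bound for Sialb.0062s0109 depends on water replicate 3, without which it was at least 27.6-fold lower, and that for Sialb.0188s0410 was at least 77.1-fold higher without Ag NP replicate 3. The number of changed genes was 435 without water replicate 2, 347 without water replicate 3, 364 without Ag NP replicate 2, 391 without Ag NP replicate 3, 223 when only the 2 groups were fitted, 224 at an adjusted p under 0.01 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 1920 by DESeq2, of which 913 rose and 1007 fell. More genes rose than fell, 467 against 334, without water replicate 1, so the larger number of falls depends on that library.

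Ag NPs in calcium nitrate changed 1614 genes, with 764 that rose and 850 that fell, at median log2 fold changes of 1.2 and -1.26. Sialb.1249s0009 rose from 0.444 ± 0.456 CPM to 50.8 ± 24 CPM (SD, n = 3 each), a log2 fold change of 6.80 ± 0.85 (SE). Sialb.0858s0003 rose from 0.714 ± 0.631 to 73.8 ± 20.2 CPM, a log2 fold change of 6.65 ± 1.14. Sialb.0087s0035 fell from 4.88 ± 2.11 to 0.0878 ± 0.118 CPM, and Sialb.0319s0039 fell from 1.99 ± 1.38 to 0.042 ± 0.0727 CPM, where only 2 reads were left over the 3 libraries.

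Adjusted p values were 0.00221, 0.00926, 0.00954 and 0.0363 for these 4 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Sialb.1249s0009 and Sialb.0858s0003 both had sums that were not whole in 11 of the 12 libraries, so their reads are partly shared with other models and their levels are uncertain. The call of Sialb.0319s0039 was lost without any 1 of calcium nitrate replicates 2 and 3 or Ag NP replicates 1, 2 and 3, with edgeR's Benjamini-Hochberg adjusted p between 0.0628 and 0.129 and log2 fold changes between -8.40 and -4.93, against -5.58 with all libraries. The count of changed genes was 789, 997 and 1068 without calcium nitrate replicates 1, 2 and 3, and 789 and 877 without Ag NP replicates 1 and 2. The balance of rises and falls turned without calcium nitrate replicate 2, to 528 that rose and 469 that fell, and by DESeq2, to 1514 and 1435 of 2949.

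Calcium nitrate alone against water gave the largest count among these comparisons, with 2655 changed genes, and more of them fell than rose, 1718 against 937. Of all tested genes 8.38% changed, from 3.86% of those with a mean under 1 CPM to 17% of those at 100 CPM or more. The balance differed with abundance, with 76 that rose and 55 that fell under 1 CPM, 390 and 514 from 1 to 10 CPM, 417 and 900 from 10 to 100 CPM, and 54 and 249 at 100 CPM or more. Sialb.0557s0029 had no reads in water and 8.35 ± 0.663 CPM (SD, n = 3) in calcium nitrate, at least 224-fold higher, and Sialb.0214s0048 went from no reads to 4.93 ± 0.945 CPM, at least 132-fold higher. Neither gene had a read in the water libraries with Ag NPs, and both were present in calcium nitrate with Ag NPs, at 4.77 ± 0.251 and 3.95 ± 1.28 CPM. Sialb.0089s0011 fell from 6.68 ± 0.558 to 0.0206 ± 0.0356 CPM, which is 1 read over the 3 libraries, and Sialb.0006s0036 fell from 7.7 ± 0.995 to 0.0906 ± 0.0815 CPM.

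By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p values of these 4 genes were 5.44e-05, 0.000499, 0.0012 and 0.00101. All 4 kept their direction and their call in each of 8 alternatives. The count of changed genes was 1391 without calcium nitrate replicate 1, 1737 without calcium nitrate replicate 3, 1603 without water replicate 3, 1707 when only the 2 groups were fitted and 4143 by DESeq2.

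**Figure D2:**
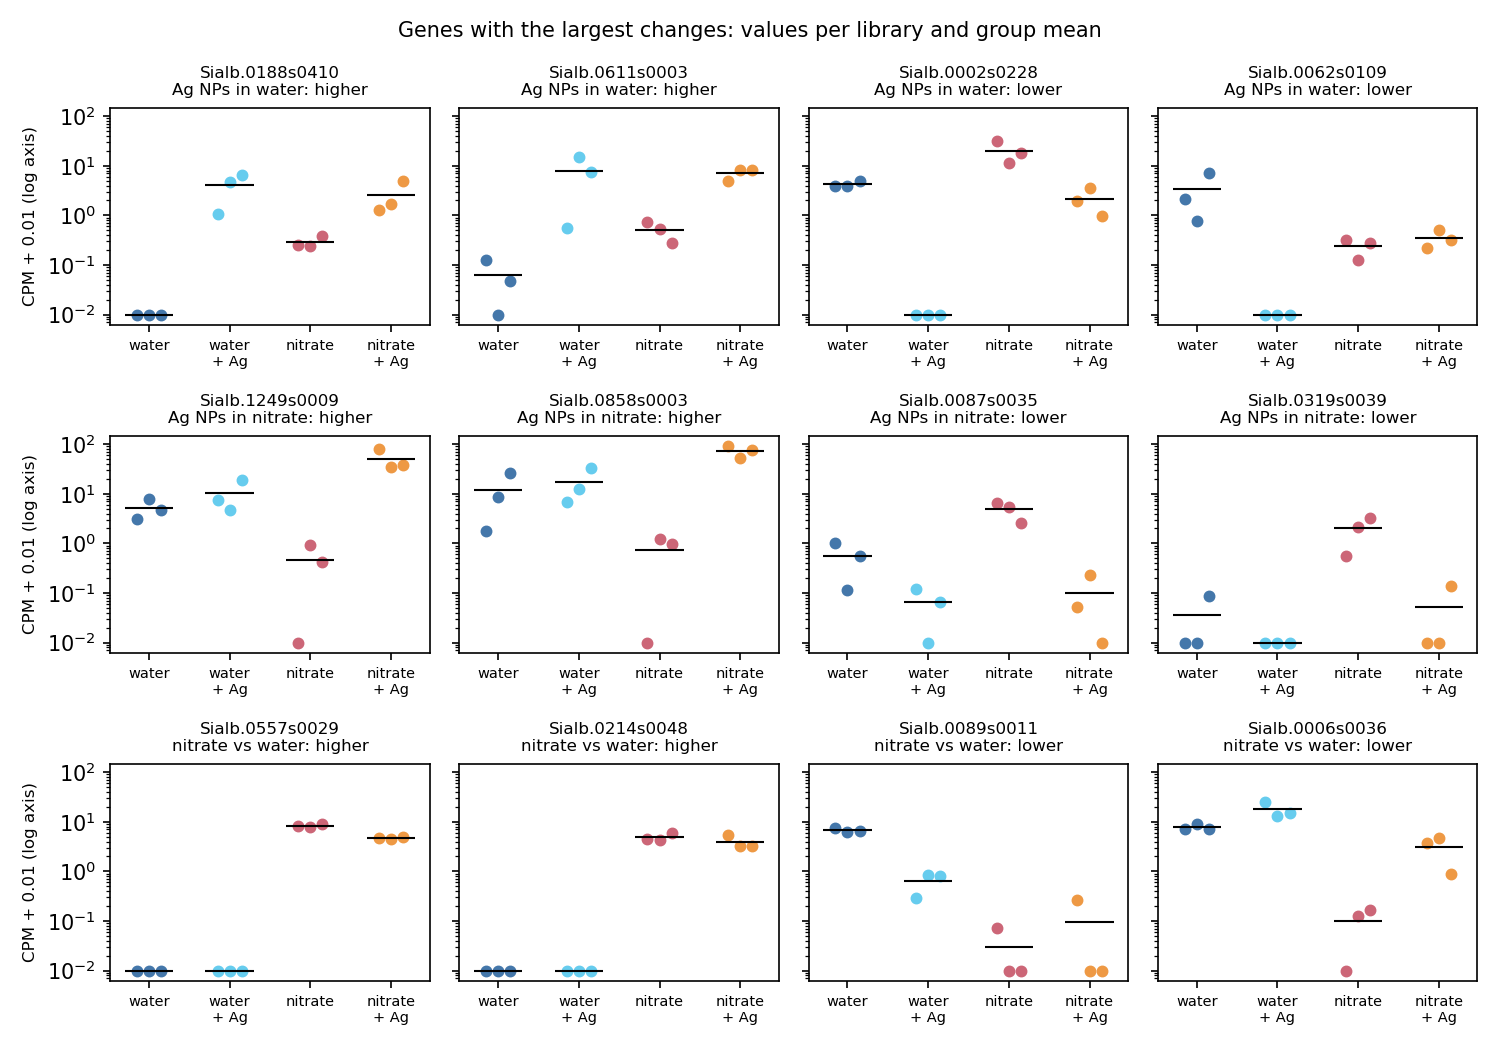
CPM per library, plus 0.01 on a log axis, of the genes named for Ag NPs in water, Ag NPs in calcium nitrate and calcium nitrate against water, with the group mean as a bar, so that points at the bottom have 0 reads. Sialb.0557s0029 and Sialb.0214s0048 are at 0 in all 6 libraries without calcium nitrate.

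Both treatments together against water changed 2177 genes, of which 815 rose and 1362 fell. Sialb.0557s0029 was again among the largest rises, from no reads to 4.77 ± 0.251 CPM (SD, n = 3), at least 128-fold higher. Sialb.0025s0228 rose from no reads to 4.58 ± 1 CPM and stood at 4.57 ± 1.42 CPM in calcium nitrate without Ag NPs. Sialb.0198s0039 fell from 3.14 ± 0.788 CPM to no reads, at least 60.6-fold lower, and Sialb.0245s0029 fell from 2.02 ± 1.28 CPM to no reads, at least 39-fold lower.

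The adjusted p values of the 4 genes were 8.91e-05, 0.000589, 0.00746 and 0.0284 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The call of Sialb.0245s0029 was lost without any 1 of water replicates 1 and 3 or of the 3 libraries with both treatments, with edgeR's Benjamini-Hochberg adjusted p between 0.0594 and 0.0777 and fitted log2 fold changes between -8.42 and -8.00, against -8.39 with all libraries. Its bound was at least 30.6-fold lower without water replicate 3. The count of changed genes was 1275 without water replicate 3, 1085 and 1342 without replicates 2 and 3 of the combined treatment, 1415 when only the 2 groups were fitted and 3606 by DESeq2.

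The responses to Ag NPs in water and in calcium nitrate, which share no libraries, overlapped in direction. Of the genes that fell with Ag NPs in water, 279 also fell in calcium nitrate, where independent lists would share 12.2, and of those that rose, 60 also rose, where independent lists would share 8.63. No gene rose in water and fell in calcium nitrate, and 1 gene, Sialb.0866s0017, named after its values were seen, fell in water and rose in calcium nitrate. The 455 genes that fell in water had a median log2 fold change of -1.02 in calcium nitrate, and 93.4% had the same sign there. The 358 genes that rose in water had a median of 0.56 in calcium nitrate, with 85.8% of the same sign.

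Across all 31675 genes, which are not independent replicates, the log2 fold changes of the Ag NP effect in the 2 media had a Pearson correlation of 0.33 and a Spearman correlation of 0.29. Over the genes called in either medium, the Pearson correlation was 0.56.

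**Figure D3:**
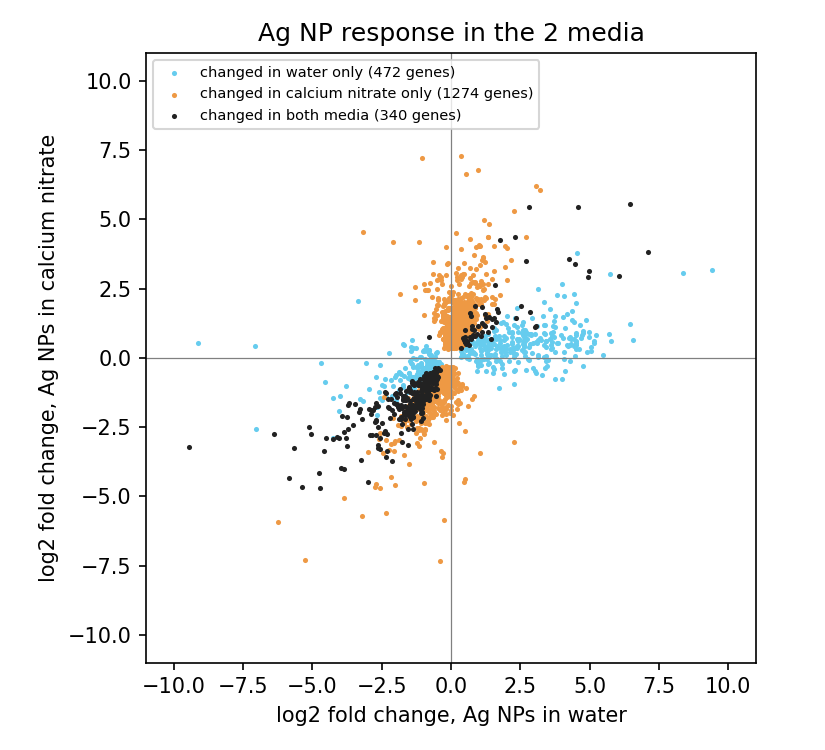
Log2 fold change by Ag NPs in water against that in calcium nitrate for genes called changed in at least 1 medium, with 1 point per gene. The 340 genes called in both media have the same sign in both, apart from Sialb.0866s0017.

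Whether the Ag NP effect depended on the medium was tested as an interaction. No gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where the smallest adjusted p was 0.0577. At an unadjusted p under 0.05 the same test gave 3254 genes, 10.3% of those tested. DESeq2 called 622 genes and limma-voom 0. By edgeR, 27 genes were called without replicate 1 of Ag NPs in water, and 26 when only genes with whole sums were fitted, a setting chosen after the data were seen. In simulated data of this depth and spread, edgeR recovered 41% of genes with a 4-fold interaction and 3% of those with a 2-fold interaction. The lack of calls therefore does not exclude differences between the media, 4-fold ones included.

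Many genes called changed by calcium nitrate were called in the opposite direction when Ag NPs were added to it. Of the 1718 genes that fell with calcium nitrate, 453 rose when Ag NPs were added to calcium nitrate, where independent lists would share 41.4, and of the 937 that rose, 137 fell, against 25.1. Sialb.0006s0036 was among the 453, with 0.0906 ± 0.0815 CPM in calcium nitrate and 3.15 ± 2.02 CPM with Ag NPs added (SD, n = 3 each, log2 fold change 4.99 ± 0.77, adjusted p 0.00577 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In the same direction as calcium nitrate, 11 genes rose in both comparisons, against 22.6, and 24 fell in both, against 46.1. In water, Ag NPs and calcium nitrate raised 146 genes in common, against 10.6 for independent lists, and lowered 60 in common, against 24.7. In opposite directions, 40 genes rose with calcium nitrate and fell with Ag NPs, against 13.5, and 17 fell with calcium nitrate and rose with Ag NPs, against 19.4.

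Both of these overlaps rest on comparisons that share 3 libraries, so part of the excess may come from the shared libraries. With no effects, simulated groups against the shared calcium nitrate libraries gave a correlation of -0.51 and a covariance of -0.089, against an observed -0.47 and -0.218. For the shared water libraries the simulated values were 0.49 and 0.083, against 0.31 and 0.143. The covariance differed from the simulated one by -0.129 and 0.06. When the 3 shared libraries were divided so that 1 library served 1 comparison and the remaining 2 served the other, the covariance over the 6 divisions had a mean of -0.135 (-0.155 to -0.111) for calcium nitrate and 0.044 (0.008 to 0.065) for water. The mean correlation over the divisions was -0.24 for calcium nitrate and 0.08 for water. Dividing the libraries does not remove an offset common to all 3 of them. The overlaps of calls were not recomputed with divided libraries.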

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

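The tests in held-out libraries and the splits for the interaction were chosen after the data were seen. Among the held-out tests, only the one after thinning over both directions had its prediction set before its own result. DESeq2 called 622 genes whose response to Ag NPs differed between water and calcium nitrate, among 32598 genes kept by its own filter. Over 31675 genes, the same contrast gave 0 genes by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3254 by edgeR at an unadjusted p under 0.05, and 0 by limma-voom. Over 25 assignments of the Ag NP labels within each medium, the real one included, the highest other gave 20 genes by edgeR. All 25 reach a real count of 0 by construction, so the splits decide nothing about the interaction.

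In 4 named genes all libraries with a treatment lay on one side of those without it in 1 background. In the other background they lay on the opposite side. Sialb.0866s0017, chosen after its values were seen, fell with Ag NPs in water from 29.4 ± 2.44 to 17.1 ± 2.07 CPM and rose in calcium nitrate from 9.46 ± 0.646 to 16 ± 1.71 CPM (SD, n = 3 each). The difference between its Ag NP effects was 1.54 ± 0.17 on the log2 scale (SE), with an adjusted p of 0.0577 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and its sums were not whole in 11 libraries. For the other 3 genes, mean CPM in calcium nitrate was below that in water without Ag NPs and above it with Ag NPs. These 3 genes were named for large Ag NP changes in 1 medium. That choice favours opposite calcium nitrate effects, so their pattern is partly built in. The difference between the calcium nitrate effects was 9.67 for Sialb.0062s0109, which had no reads in water with Ag NPs, so that this value depends on the prior count. It was 5.82 for Sialb.1249s0009 and 6.09 for Sialb.0858s0003. None passed edgeR's quasi-likelihood test of that difference, with Benjamini-Hochberg adjusted p values of 0.132, 0.0897 and 0.15.

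Calcium nitrate changed 619 genes in the libraries with Ag NPs, a comparison neither planned nor repeated under the other settings, against 2655 without. The genes it changed without Ag NPs had median log2 fold changes of 1.40 and -1.05 there and of 0.44 and -0.41 with Ag NPs. Choosing genes on the libraries without Ag NPs enlarges this gap. The genes called with Ag NPs had medians of 1.62 and -1.05 there and of 1.13 and -0.83 without Ag NPs. The gap between these medians thus reversed with the choice of genes. With genes chosen on both Ag NP levels alike and measured in held-out libraries, lowered genes had medians of -1.31 without and -0.85 with Ag NPs, and a ratio of 0.60 that was below 1 in all 81 combinations and stayed at 0.60 after thinning to 15.2 M reads, which argues against selection and depth as the whole cause. For raised genes, at 1.45 and 1.27, selection and depth stay open. Their ratio had a median of 0.81 as deposited and after thinning. It was at or above 1 in 11 of the 81 combinations as deposited and in 8 after thinning. Over both directions the ratio was 0.74 (0.47 to 0.96), and 0.73 after thinning. A single unusual library stays open too, since with each library left out of both choice and measurement the median was at most 0.67 for lowered genes, 0.88 for raised genes and 0.76 for both, but the ratio was at or above 1 in 6, 95 and 6 of 648 combinations. The combinations reuse 12 libraries, so no p-value is given, and an unrecorded difference in handling between the groups was not tested.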

How the results depend on the processing

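The counts of changed genes depended on the setting, and the cause was not tested except where fewer genes or libraries entered. In the order Ag NPs in water, Ag NPs in calcium nitrate, calcium nitrate and both treatments, the counts were 813, 1614, 2655 and 2177. DESeq2 gave 1920, 2949, 4143 and 3606, and 622 for the interaction in place of 0, with 32598 to 34976 genes kept by its own filter. A threshold of 0.01 on the adjusted p gave 224, 473, 992 and 753. An absolute log2 fold change of at least 1 left 1012 for Ag NPs in calcium nitrate, 1517 for calcium nitrate and 1311 for both. A fit of only the 2 groups, with fewer libraries for the spread, gave 223 for Ag NPs in water, 1707 for calcium nitrate and 1415 for both. Restricting the fit to genes with whole sums, chosen after seeing the data, left 12347 genes and gave 498, 925, 1189 and 1156, and 26 for the interaction. The main fit had called 347, 680, 988 and 924 of its 12362 genes with whole sums, fewer than this refit in each comparison. Leaving out 1 library at a time gave 347 to 801, 789 to 1144, 1391 to 2028 and 1085 to 1633, and 0 to 27 for the interaction, where 27 came without replicate 1 of Ag NPs in water. Without water replicate 1, 58.3% of the genes changed by Ag NPs in water rose, against 44% with all libraries. The balance of rises and falls also turned for Ag NPs in water at an absolute log2 fold change of at least 1 (291 and 286), and for Ag NPs in calcium nitrate by DESeq2 (1514 and 1435), without calcium nitrate replicate 2 (528 and 469) and over whole-sum genes (468 and 457). The correlation of Ag NP effects between media was 0.33, 0.56 over called genes, 0.40 over whole-sum genes and 0.26 to 0.32 with 1 library left out. DESeq2's size factors moved the median log2 fold change by at most 0.013. Of 128 alternatives for the named genes, 115 kept direction and call, 13 kept the direction only and 0 reversed. Other settings, among them limma-voom, other filters, unsummed models and, chosen after seeing the data, thinning and effective lengths, kept counts within 1.5 times. The other settings chosen for tests of the gene lists were not run, since the lists matched no identifier. No paired analysis was possible because the labels give the groups no shared replicate numbers. Of the 10 splits of 6 libraries, too few for a share under 0.05, only the real 1 reached its count in each comparison, and the highest others gave 2, 1, 0 and 2 genes. At this depth, spread and number of libraries, 23% to 34% of simulated 2-fold changes were recovered, with few genes changed per simulation. Thinning to 15.2 M reads gave 744, 1603, 2560 and 2045 genes.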

Other observations

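The tests of the 7 short genes were chosen after their values were seen, and the count of consecutive identifiers was devised after the data were seen, with its 2 tests of explanations set before their results. Ag NPs had a smaller count of changed genes in water than in calcium nitrate. Of the genes called in calcium nitrate, 32.8% of those that fell and 7.85% of those that rose were also called in water. Most of the rest had the same sign there. The 850 that fell had a median log2 fold change of -0.72 in water, with 94.4% of the same sign, and the 764 that rose had a median of 0.30, with 78.7%. Calcium nitrate in the presence of Ag NPs raised 323 genes and lowered 296, of which 205 and 199 also rose and fell without Ag NPs, where independent lists would share 9.55 and 16.1. These comparisons share no libraries.

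Genes with consecutive identifier numbers changed together more often than shuffled calls. Under calcium nitrate, 168 pairs of consecutive identifiers changed in the same direction, against a mean of 81.7 over 1000 shuffles, whose highest was 109. Reads split between near-identical neighbours mostly leave sums that are not whole, yet genes with whole sums gave 32 pairs against a highest shuffle of 29, or 2.06 times the shuffled mean, which argues against such splitting as the whole cause, though a whole sum does not exclude sharing. Shuffling within 20 abundance classes left 1.96 times the mean, which argues against similar abundance of neighbours. Ag NPs gave 34 pairs in water against a mean of 7.26 and 73 in calcium nitrate against 27.9. A candidate explanation is shared regulation of neighbouring or duplicated genes, which was not tested, since positions and sequences were not used here.

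The most abundant gene by mean TPM, Sialb.1411s0013, with a coding length of 282 bases, ranged 10.1-fold between libraries, from 654 CPM in calcium nitrate replicate 2 and 717 in water replicate 1 to 6580 in water replicate 3. The deviations from the group means of 6 other genes of 210 to 345 bases each correlated with its own above 0.95. These 6 were chosen for this and for a standard deviation of their deviations above 0.5 on the log2 scale. None of the 7 was called changed, with a smallest Benjamini-Hochberg adjusted p of 0.302 by edgeR's quasi-likelihood test. Choosing genes for a large spread within groups makes such a call unlikely. The median deviation of the 7 ran from -1.71 to 1.36 on the log2 scale, while that of 1475 other genes of such lengths stayed within 0.12 of 0, which argues against a loss of all short transcripts in some libraries. Reads shared between near-identical models cannot be told apart from a common source, since 1 of the 7 genes had whole sums in all 12 libraries and 6 had not. Length minus effective length of long models was taken as fragment size. Over the 12 libraries it had a Pearson correlation of -0.4 with the median deviation of the 7 genes (permutation test, p 0.19). Without the 2 libraries farthest from the median fragment size the correlation was -0.27. Fragment size thus stays open as a cause. No biological explanation was tested.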
